A study of Mus musculus with 2 samples.

How the data were processed

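H3K27ac, an acetylation of histone H3 found at active promoters and enhancers, was mapped by chromatin immunoprecipitation and sequencing in liver from mouse embryos at day 14.5, pooled from both sexes per the labels. The labels name 1 group with 2 biological replicates. Replicate 2 combined 2 technical replicates and replicate 1 held 1. The labels give a fragment size range of 300 to 500 bp. Because there was no second condition, no comparison between conditions was made.

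The starting material was 4 deposited peak lists in mm10 coordinates: 1 for each replicate, 1 called on the alignments of both replicates together (the pooled list), and 1 made from the pooled list and both replicate lists (the replicated list), per the file notes. The aligner, the peak caller, its thresholds and the overlap rule of the replicated list are not given in the sources used here. Per the file notes, the replicate 1 and pooled lists were derived from 1 more input file than the replicate 2 list, and its role is not stated. The signal deposited for each peak is an enrichment on a linear ratio scale. The deposited −log10 p-value and −log10 q-value of each peak follow in further columns, and the deposited summit position is an offset from the start of the peak. That the ratio is over a control sample is the usual meaning of this format and is not stated for these files. All 4 lists hold peaks with a −log10 p of at least 2, and some peaks have a q-value above 0.05. The deposited signal is the authors' own value for a peak, used here to describe, rank or filter peaks within a list, to compare peak ranks between the replicates, and to compare promoters within the replicated list. Read counts are not in the peak lists, so the depth of each replicate is unknown, and a region without a peak was not shown to lack the mark. Intervals given for shares of peaks are 95% Wilson binomial intervals and cover counting error only.

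Coordinates were compared with GRCm38, the assembly behind mm10. No peak, 0 in all lists together, ran past a chromosome end. Gene models were 21938 protein-coding genes of GENCODE release M 21 on chromosomes 1 to 19, X and Y, with 93513 transcript start sites. Peaks outside these chromosomes were left out of the comparisons: 3 of replicate 1, 1 of replicate 2, 2 of the pooled list and 2 of the replicated list. All symbols of the 23 gene lists matched a gene, and 0 of them named more than 1 gene. Olfactory receptor genes, taken beforehand as largely silent in liver, formed a further list, making 24. No deposited column of sample values was left unused.

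A peak counted as shared when it overlapped a peak of the other list by 50% of the length of either peak. Chance overlap came from 100 circular shifts of a list along its chromosomes. Rank agreement was Spearman's rho across peaks paired one to one, with no p-value because peaks are not independent replicates. A promoter peak overlapped 1000 bp either side of a start site of a protein-coding transcript, and all other peaks were called distal. Marking of promoters in each list was compared with all other protein-coding genes by 2-sided Fisher's exact tests. Distal marking was the number of distal peaks within 50000 bp of a gene's start sites, compared with 10000 random lists matched on the tertile of promoter CpG content (observed over expected, 500 bp either side) and of local gene number, as a 2-sided permutation test. Motifs were consensus sequences searched on both strands within 250 bp of summits of distal peaks and in equal windows 10000 bp away that held no peak of any list, compared by 2-sided Fisher's exact tests. Each motif written backwards, not complemented, served as a control for base composition. Distal peaks closer than 12500 bp were joined and ranked by the sum of signal times length. Each family of tests was adjusted by the Benjamini-Hochberg method over its 24 lists or 13 motifs, with a threshold of 0.05. Tests of gene families taken from symbols were adjusted in the same way over those families alone. Genes, peaks and windows were the units of these tests, not animals, so their p-values do not measure the spread between animals. For that reason the values of both replicates stand beside many of the p-values, though not beside all. Genes of a cluster were counted as separate units, so p-values of clustered lists can overstate the evidence. The smallest adjusted permutation p-values come from the smallest raw value that the random lists can give, 2e-04.

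Genes named in the text followed a rule: from each list, up to 3 members with the highest promoter signal in the replicated list and up to 2 members without a promoter peak there, the first in list order. The 5 strongest peaks, the 5 highest ranked joined regions and 6 loci (Alb-Afp, Hbb, Hba, Gata1, Hnf4a and Apoa1) were named whatever their values. Lists, motifs, tests, the naming rule and the following other settings were fixed before the data were examined. The settings were a −log10 q of at least 5, overlaps of 1 bp or of 50% of both peaks, promoter windows of 500 and 2500 bp, CpG-matched random lists, 5' gene ends only, distances of 20000 and 100000 bp, no matching, motif windows of 100 bp, flanks 2000 bp from peak edges, joining within 5000 bp, each replicate's list alone, and the pooled list. Restriction to peaks found in both replicate lists and counting neighbouring genes once were added after the data were seen.

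The code was tested on simulated data. Simulated lists of 20 genes marked at 85% or at 5% against 40% were called in 100% of 40 simulations each, and lists at the background rate in 5%. Lists with 3 times the average gene's number of distal peaks added per gene were called in 100% and random lists in 5%. GATA motifs planted in 30% of windows were called, with 0 other motifs called. Members of simulated lists were drawn at random, so these rates do not cover lists that are clustered or skewed in CpG content. Simulated distal calls used unadjusted p-values, and effects smaller than those simulated were not tried. The tools were Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, pysam 0.24.0, matplotlib 3.10.9, bedtools 2.31.1 and samtools 1.23.1.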

Results

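H3K27ac peaks were described in liver from mouse embryos at day 14.5, a stage at which the liver is a site of blood formation as well as a developing metabolic organ. The data were the peak lists of 2 biological replicates, each from a pool of mixed sex, and lists made from both. Replicate 1 held 34760 peaks with a median width of 379 bp, covering 24287138 bp or 0.891% of the genome. Replicate 2 held 26397 peaks with a median width of 444 bp, covering 19879258 bp or 0.729% of the genome. The replicated list held 26594 peaks with a median width of 565 bp, covering 25130807 bp or 0.922% of the genome, and the pooled list held 32189. The longest peak of the replicated list spanned 21007 bp. The most significant peak had a −log10 p of 148.6 in replicate 1 and 68.8 in replicate 2, and 11.9% and 30.7% of the peaks had a q-value above 0.05. In the replicated list 2485 peaks, or 9.34%, had a q-value above 0.05. Depth is unknown, since the lists hold no read counts.

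The first question was how far both replicates marked the same regions. Regions of high signal were found in both lists, while weak regions often appeared in 1 list. Of 34757 replicate 1 peaks on assembled chromosomes, 21311 overlapped a replicate 2 peak (61.3%, 95% Wilson interval 60.8 to 61.8), against a mean of 1.09% and a maximum of 3.20% in random placements. Of 26396 replicate 2 peaks, 23066 overlapped a replicate 1 peak (87.4%, interval 87.0 to 87.8), against a mean of 1.43% and a maximum of 2.52%. Recovery of replicate 1 peaks in replicate 2 was 29.7% in the decile of weakest signal, 26.9% in decile 3, 64.4% in decile 6, and 100% in the strongest decile. Across 19998 peaks paired one to one, signal ranks had a Spearman's rho of 0.776, a value across peaks and not across animals. The 2 lists shared 17911937 bp, a Jaccard index of 0.682. Requiring 50% of both peaks lowered the share of replicate 1 peaks to 47.2% and that of replicate 2 peaks to 62.1%.

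**Figure D1:**
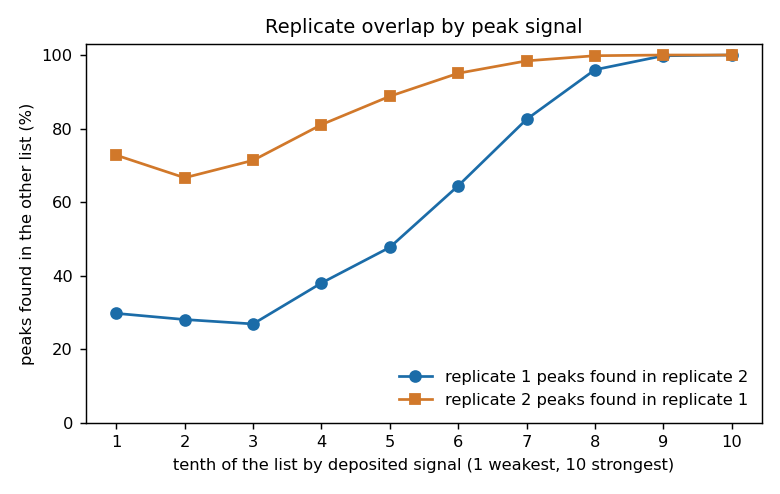
Share of peaks found in the other replicate's list (vertical axis, percent) by decile of deposited signal within each list (horizontal axis), circles for replicate 1 peaks and squares for replicate 2 peaks. Recovery of replicate 1 peaks was lowest in decile 3 (26.9%) and that of replicate 2 peaks in decile 2 (66.6%), and both reached 100% in the strongest decile.

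Peaks found in 1 replicate lay away from promoters more often than shared peaks. The 13446 peaks of replicate 1 alone were at promoters in 27%, against 51.3% of shared peaks (odds ratio 2.84, 95% interval 2.72 to 2.98). The 3330 peaks of replicate 2 alone were at promoters in 35.9%, against 49.4% of shared peaks (Fisher's exact test, p = 4.79e-49). Replicate 1 peaks found alone had a median signal of 3.37 and a median width of 230 bp, against 5.19 and 618 bp for shared ones.

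The next question was where the marked regions lie. In the replicated list 12617 of 26592 peaks, or 47.4%, overlapped the promoter of a protein-coding gene, against a mean of 5.50% and a maximum of 6.33% in random placements. The share was 41.9% in replicate 1 and 47.7% in replicate 2. Introns of protein-coding genes held 29.1% of the peaks and intergenic sequence 16.6%. Promoter peaks had a median signal of 5.06 and the 13975 distal peaks one of 3.93. Marked promoters belonged to 8284 of 21938 protein-coding genes (37.8%), with 38.2% in replicate 1 and 35.7% in replicate 2. They made up 8.68% of genes in the lowest tertile of promoter CpG content, 35.6% in the middle and 69.0% in the highest.

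Promoters of red cell genes were the most widely marked of the cell type lists. All 12 genes of heme synthesis and all 10 globin genes had a promoter peak, as did 22 of 23 erythroid genes, with the same counts in each replicate (Fisher's exact test, adjusted p = 2.87e-05, 1.76e-04 and 4.30e-08). The globin genes lie in clusters, so their promoters are not independent. The erythroid genes with the highest signal were Ank1, encoding the ankyrin of the red cell membrane skeleton (32.1, peak at chromosome 8, 23049129 to 23060499), Trim10 (22.0) and Epb42, encoding the membrane protein 4.2 (21.2, chromosome 2, 121034336 to 121038061). Replicates 1 and 2 gave 25.1 and 16.4 at Ank1, 23.6 and 13.6 at Trim10, and 22.1 and 14.1 at Epb42. The Ank1 peak lay at an internal start site and not at the 5' end of the gene, and 19 of 23 erythroid genes were marked at 5' ends. The signal of a wide peak belongs to its summit, which can lie over 1000 bp from the start site. Slc25a37, the mitochondrial iron importer mitoferrin, was the erythroid gene without a promoter peak, in either replicate. Among heme genes, signal was 29.5 at Fech, which inserts iron into the porphyrin ring, 29.4 at Hmbs and 23.9 at the glycine carrier Slc25a38. The median signal of marked genes was 18.3 for heme synthesis, 17.8 for erythroid genes and 9.45 for globins. The adult alpha-globin genes Hba-a1 and Hba-a2 had signals of 14.9 and 18.2, and Hbq1b had 21.2. The Hba-a1 and Hba-a2 values came from peaks that began in the last bases of each gene and extended downstream of it. Peaks also lay 60 bp upstream of the Hba-a1 start and 220 bp upstream of the Hba-a2 start, with lower signals in the replicated list. Hba-a1 and Hba-a2 are near-identical copies, so how reads were divided between them is uncertain.

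Genes of hepatocytes, the main cell of the adult liver, stood at or below the background. Among secreted proteins, 6 of 20 promoters were marked (30.0%, against 37.8% of other genes, adjusted exact p = 0.738), with 9 in replicate 1 and 6 in replicate 2. The highest signals were 4.84 at Rbp4, which carries retinol in plasma, 3.62 at Apoa2 and 3.47 at Apob, the structural protein of very low density lipoprotein. Ttr and Apoa1 had no promoter peak in the replicated list, and Apoa1 had one in replicate 1. Among hepatic transcription factors 5 of 16 were marked (adjusted exact p = 0.821): Nr5a2 (4.58), Creb3l3 (3.96) and Foxa2 (3.27) were highest, while Hnf4a and Hnf1a had no promoter peak. Replicate 1 alone gave a peak at Nr5a2 (5.79) and replicate 2 alone at Foxa2 (3.04), and the marked members numbered 5 and 4. Coagulation and complement genes were marked in 2 of 23 (adjusted exact p = 0.00527), F10 (3.76) and Cfi (3.07, found in replicate 1 alone), with F5 and F7 unmarked, and in 4 and 1 in replicates 1 and 2. Mature hepatocyte metabolism was marked in 2 of 24 (adjusted exact p = 0.00355), at Glul, the glutamine synthetase gene (13.6), and Hpd (3.68), while Cyp3a11 and Cyp2e1 were unmarked, with 3 and 2 in the replicates. The Creb3l3 and Hpd peaks lay at internal start sites, and at 5' ends 3 of 16 hepatic transcription factors and 1 of 24 mature hepatocyte genes were marked. Against random lists of the same CpG class neither low share stood apart (permutation test, adjusted p = 0.795 and 0.469, the highest of ranges that began at 0.00128 and 6.86e-04 over all settings tried). Coagulation and complement did not pass in replicate 1 alone (adjusted exact p = 0.0649). With only peaks at a −log10 q of at least 5, the lists of secreted proteins and hepatic transcription factors fell below other genes (adjusted exact p = 0.0297 and 0.0140). Cholesterol synthesis, which most growing cells need, was marked in 17 of 21 genes (adjusted exact p = 2.47e-04), with signals of 11.8 at its regulator Srebf2, 11.6 at Fdft1 and 10.4 at the receptor gene Ldlr. Lss and Cyp51 were unmarked, although replicate 1 alone gave a peak at Cyp51 (3.69).

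**Figure D2:**
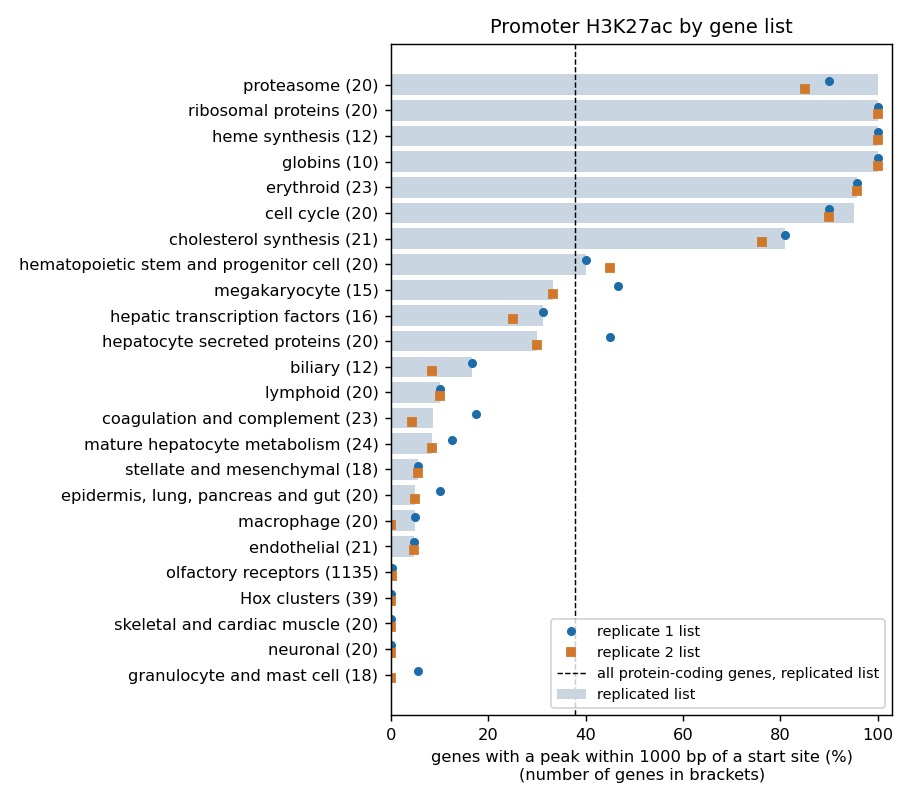
Share of genes with a peak within 1000 bp of a start site (horizontal axis, percent) in each gene list, as bars for the replicated list, circles for the replicate 1 list and squares for the replicate 2 list. The dashed line is the 37.8% of all protein-coding genes; globins, heme synthesis, ribosomal proteins and proteasome reached 100% in the replicated list, and Hox clusters had 0.

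Lists of other blood lineages came next. Stem and progenitor genes were marked in 8 of 20 (adjusted exact p = 0.821), with high signal at the transcription factors Lmo2 (26.7), Lyl1 (19.8) and Tal1 (13.8) and none at Kit or Cd34. The replicates marked 8 and 9, and signal at Lyl1 was 8.06 in replicate 1 and 15 in replicate 2. Megakaryocyte genes were marked in 5 of 15 (adjusted exact p = 0.821), with 18.1 at Gp9, 17.4 at Vwf and 12.7 at Gp1ba, and none at Pf4 or Gp1bb. The replicates marked 7 and 5. The Vwf peak lay at an internal start site. Macrophage genes were marked in 1 of 20, Cd68 (2.45, found in replicate 1 alone), with none at Adgre1 or Csf1r (adjusted exact p = 0.00286). Granulocyte and mast cell genes were marked in 0 of 18, Mpo and Elane included, although replicate 1 alone gave a peak at Mpo (adjusted exact p = 5.90e-04), and lymphoid genes in 2 of 20, Vpreb1 (9.28) and, at an internal start site, Lck (8.12), with none at Cd19 or Cd79a (adjusted exact p = 0.0124). Against CpG-matched lists these last 3 no longer passed (permutation test, adjusted p = 0.504, 0.164 and 0.432), and lymphoid genes did not pass at a −log10 q of at least 5 (adjusted p = 0.0941).

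Lists of other liver cells had few marked members. Endothelial genes were marked in 1 of 21, Eng (3.69, found in replicate 2 alone), with none at Pecam1 or Cdh5 (adjusted exact p = 0.00191). Stellate and mesenchymal genes were marked in 1 of 18, Reln (17.4, with 5.94 and 13.5 in the replicates), with none at Col1a1 or Col1a2 (adjusted exact p = 0.00421). Biliary genes were marked in 2 of 12, Aqp1 (7.49), a water channel that red cells also carry, and Sox4 (3.41, found in replicate 1 alone), with none at Krt7 or Krt19 (adjusted exact p = 0.278). The replicates marked 2 and 1 of the biliary genes.

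Lists of other tissues and of general cell functions bounded the range. Neuronal genes such as Neurod1 and Neurod2, and muscle genes such as Myod1 and Myf5, were marked in 0 of 20 each (adjusted exact p = 2.28e-04 for both). The list of epidermis, lung, pancreas and gut was marked in 1 of 20, Krt10 (5.46, at an internal start site), with none at Krt5 or Krt14 (adjusted p = 0.00286, and 0.164 in a permutation test against CpG-matched lists). Hox cluster genes, Hoxa1 and Hoxa2 among them, were marked in 0 of 39 (adjusted exact p = 5.46e-08). Olfactory receptor genes were marked in 2 of 1135, Olfr575 (7.10) and, at an internal start site, Olfr56 (6.98), with none at Olfr1416 or Olfr1415 (adjusted exact p = 1.11e-235). Hox and olfactory receptor genes lie in clusters, so their members are not independent and these p-values overstate the evidence. Ribosomal protein genes were marked in 20 of 20, with 13.4 at an internal start site of Rpl3, 12 at Rpl7 and 11 at Rps9 (adjusted exact p = 2.74e-08), and in 19 at 5' ends. Proteasome genes were marked in 20 of 20, with 15.9 at Psmc6, 12.4 at Psma5 and 11.4 at Psmc2, but in 18 in replicate 1 and 17 in replicate 2 (adjusted exact p = 2.74e-08). Cell cycle genes were marked in 19 of 20, with 13.2 at Rrm2, 12.9 at Ccna2 and 10.5 at Mcm7, and none at Mcm3 (adjusted exact p = 4.66e-07).

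Distal peaks were next counted around the same genes. Erythroid genes had a mean of 6.91 distal peaks within 50000 bp, 5.72 times the 1.21 of matched lists, and 22 of 23 had at least 1 (permutation test, adjusted p = 0.0012). The mean was 10.5 in replicate 1 and 7.74 in replicate 2. Globin genes had a mean of 14.2 against 1.21 (adjusted permutation p = 0.0012), but they lie in 2 clusters whose members share peaks. Counting neighbouring members once kept that call, but each of the 2 clusters then counted as a single unit. The Hbb locus, with 50000 bp on either side, held 25 distal peaks and the Hba locus 5. Heme synthesis genes had 4.50 against 1.67 (adjusted permutation p = 0.0528), and passed in each replicate's list alone (0.00288 in replicate 1 and 0.0490 in replicate 2), but not at a −log10 q of at least 5 (0.442), with peaks in both replicate lists (0.114) or within 100000 bp (0.106). Stem and progenitor genes had 3.15 against 1.24 (adjusted permutation p = 0.0744), and passed in replicate 1 (0.0160) but not in replicate 2 (0.106). Hox genes had 0 against 2.07 and olfactory receptor genes 0.164 against 0.938 (adjusted permutation p = 0.0012 for both). Hepatocyte secreted proteins had 1.20 against 1.08, hepatic transcription factors 1.19 against 1.34, coagulation and complement genes 0.522 against 0.860, and mature hepatocyte metabolism 1.71 against 0.949, of which none passed (adjusted permutation p = 0.992, 0.992, 0.933 and 0.501). The remaining 14 lists did not pass, with adjusted p-values from 0.501 to 0.992.

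The strongest single peak of the replicated list lay at the promoter of Pcx, encoding pyruvate carboxylase (chromosome 19, 4553998 to 4561644, signal 36.4). It was followed by peaks at the histone gene Hist4h4 (chromosome 6, 136802803 to 136805756, 34.6) and at Epb41, encoding the red cell membrane protein 4.1 (chromosome 4, 132075583 to 132079679, 34.6). A distal peak lay 3798 bp from a start site of Pip4k2c (chromosome 10, 127202610 to 127207757, 33.7), and another in an intron 7945 bp from a start site of Elmsan1 (chromosome 12, 84201960 to 84207614, 33.1). Joining neighbouring distal peaks gave 5284 regions, 715 of them with 5 or more peaks, and the top 100 held 22.7% of the summed signal times length. Promoter peaks were left out of this ranking, among them 17 of the 22 peaks at the Hba locus. The ranking therefore does not show how strong that locus was. The top region overlapped Bcl2l1, encoding the survival factor Bcl-xL (chromosome 2, 152784229 to 152827474, 12 peaks). The next overlapped Cpeb4 (chromosome 11, 31767871 to 31875620, 27 peaks), lay between Lao1 and the glucose transporter gene Slc2a1 (chromosome 4, 119005743 to 119055064, 16 peaks), overlapped Cd24a (chromosome 10, 43576038 to 43649931, 29 peaks) and covered the Hbb cluster (chromosome 7, 103806709 to 103878654, 25 peaks). All 5 stayed within the top 100 in each replicate's list. Of 21938 protein-coding genes, 231 lay within 50000 bp of the top 100 regions. Among them were 5 globin genes, the erythroid genes Gypa and Slc4a1, Lmo2 and Ikzf1, the granulocyte genes Mpo and Fcnb, and 7 olfactory receptor genes beside the Hbb cluster. The other lists had 0, and at so low a share a 0 in a short list shows no depletion.

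The named loci were read peak by peak. The Hbb cluster, with 50000 bp on either side, held 34 peaks, 25 of them distal. Its strongest peak lay in intergenic sequence upstream of Hbb-y, on the side of the locus control region (chromosome 7, 103869374 to 103871721), with a signal of 23.0 (25.2 in replicate 1 and 16.7 in replicate 2). Within 250 bp of its summit lay a GATA-E-box composite, a spaced pair of sites for GATA and E-box factors (103870845 to 103870859, within TTCCTGGTCCAATAGATAATA). The Hba locus held 22 peaks. Of these, 17 counted as promoter peaks and were left out of the distal counts, the joined regions and the motif tests. Among the 17 was the 21007-bp peak within Nprl3 (chromosome 11, 32238680 to 32259686, signal 31.3), the gene that houses the alpha-globin enhancers. An NF-E2 site lay near its summit (32245268 to 32245276, within GTGCCAGCTGACTCAGATCCC). The locus of Gata1, the erythroid master regulator on chromosome X, held 6 peaks with 50000 bp on either side, intergenic ones included. Its strongest peak was intronic (7969699 to 7972871, 13.4), with a GATA site at 7971502 to 7971508 within AAGGCATAGATAAGGGAATCA. The Alb-Afp locus held 3 peaks: 1 intergenic, 12581 bp from the Alb start (chromosome 5, 90448023 to 90448316, 4.30), 1 at the Alb promoter (90461549 to 90462028, 3.42, found in replicate 1 only) and 1 at the Afp promoter (90491447 to 90491983, 3.35). The Hnf4a locus held 7 peaks, of which 2 lay in introns of Hnf4a (3.23 and 2.43) and the strongest at the neighbouring gene Ttpal (7.74). The weaker intronic peak had a −log10 q of 0.918, and the peak at 163616979 to 163617286 overlapped no peak of either replicate list. The Apoa1 locus held 4 peaks, with 3 in introns of Sik3 (at most 4.32) and 1 at Zpr1 (3.24). The Sik3 peak at 46215544 to 46215738 (−log10 q of 0.608) and the Zpr1 peak overlapped no peak of either replicate list. GATA sites also lay within 250 bp of the summits of the Afp promoter peak and of the 3 Sik3 peaks. They therefore did not set the red cell loci apart. FOXA sites lay near summits at the Hbb, Hba and Apoa1 loci alike.

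**Figure D3:**
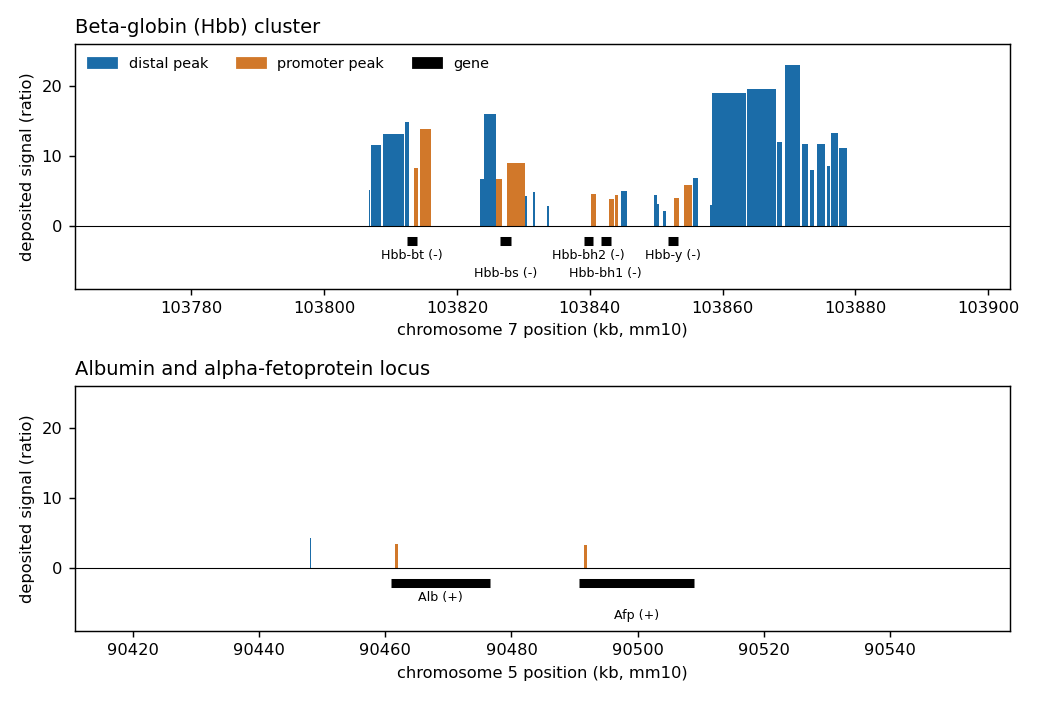
Peaks of the replicated list at the Hbb cluster (top) and the Alb-Afp locus (bottom), drawn to scale along the chromosome (horizontal axis, kb, mm10) with height as the deposited signal ratio (vertical axis, the same scale in both). Black bars are the genes of each locus, with strand in brackets; the Hbb cluster held 34 peaks reaching 23.0, and the Alb-Afp locus 3 peaks reaching 4.30.

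NF-E2, GATA and the GATA-E-box composite, motifs of blood transcription factors, had the highest odds ratios of the 13 motifs tested in distal peaks. The GATA motif lay within 250 bp of the summit in 12.4% of 13974 distal peaks against 6.48% of 22597 flanking windows (log2 odds ratio 1.03, Fisher's exact test, adjusted p = 8.38e-81), while the reversed motif had a log2 odds ratio of -0.21. The GATA-E-box composite was in 15.8% against 9.69% (0.81, adjusted exact p = 9.44e-66) and the NF-E2 motif in 3.01% against 1.27% (1.27, adjusted exact p = 5.16e-30, reversed 0.69). Reversed NF-E2 was rare, in 0.186% against 0.115%, and did not pass (adjusted exact p = 0.138), so it is a weak control. The AP-1 motif lies whole within the NF-E2 motif, so every NF-E2 match is also an AP-1 match. AP-1 was in 11.5% against 8.32% (0.52, adjusted exact p = 1.65e-23), and its reversed form had 0.13 (adjusted exact p = 0.0417). The AP-1 excess is therefore not separate from that of NF-E2. FOXA, a motif of hepatic factors, was in 18.0% against 16.0% (0.20, adjusted exact p = 4.15e-06). The KLF motif was in 7.38% against 6.27% (0.25, adjusted exact p = 9.25e-05), but its reversed form had 0.32. HNF4, HNF1, CEBP, ETS, CTCF, MEF2 and REST motifs did not pass, with adjusted p-values from 0.160 to 0.933. The CEBP, CTCF and HNF1 sequences were rare, in 40, 57 and 62 of the peaks. Their tests could miss modest differences and do not show that these factors were absent. Peaks had a mean GC content of 46.6% ± 5.66 (SD across windows) and flanks one of 44.8% ± 6.14. Within 100 bp of the summit, GATA (adjusted exact p = 0.887), NF-E2 (0.150) and FOXA (0.0656) no longer passed, KLF and CTCF were lower in peaks than in flanks (adjusted exact p = 0.0197 for both), and HNF4 passed (0.0241). HNF4 also passed against flanks 2000 bp from peak edges (adjusted exact p = 0.0130), as did ETS (0.0257), which passed in replicate 1 (4.61e-05) and not in replicate 2 (0.0871). With the main settings reversed ETS passed, with a log2 odds ratio of 0.24 (adjusted exact p = 0.0166) against 0.11 for ETS itself.

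**Figure D4:**
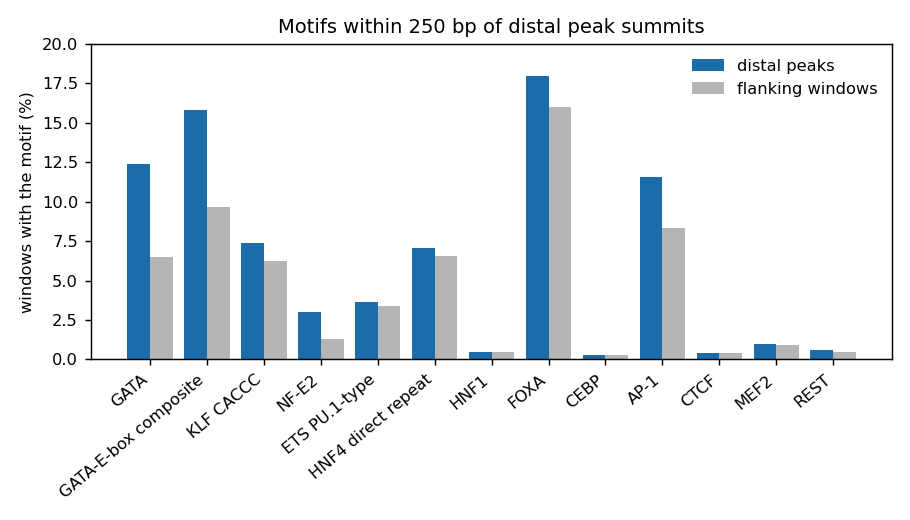
Share of windows with each motif (vertical axis, percent) within 250 bp of the summit of distal peaks and in flanking windows of equal width (paired bars per motif, horizontal axis). GATA lay in 12.4% of peaks against 6.48% of flanks and FOXA in 18.0% against 16.0%.

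Motifs near both lineages were compared directly. Distal peaks near erythroid and globin genes numbered 189 and those near hepatocyte secreted, hepatic transcription factor and coagulation genes 51. GATA lay in 12.2% of the former and 13.7% of the latter, NF-E2 in 4.23% and 0%, and FOXA in 11.6% and 21.6%. No motif passed Fisher's exact test (adjusted p from 0.552 to 1), which at these numbers does not show that they were alike.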

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

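Settings marked as added were chosen after the data were seen; all others were planned. The counts of lists above other genes at promoters stayed at 7 in all 9 alternatives, and the 4 calls of distal marking passed in all 9. Of 171 promoter values for the 19 called lists, 163 kept their call and 0 turned direction. For lists that were not called, the odds ratio, corrected for zero counts, changed sign in 7 promoter values and the difference in means in 21 distal values, none of which passed. Unless given, the cause was not tested; values for lists and motifs are adjusted p. An overlap of 1 bp gave 64.5% of replicate 1 and 90.8% of replicate 2 peaks shared, and 50% of both peaks gave 47.2% and 62.1%. At a −log10 q of at least 5 (fewer peaks by construction), 97.4% of replicate 2 peaks were shared, rho was 0.745, 59.9% of peaks were at promoters and 3014 regions were joined. The promoter share was 43.1% with 500 bp, 56.2% with 2500 bp, 52.7% with peaks in both replicate lists (added), and 41.9% to 47.7% with 1 replicate left out.

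For promoter lists, the strict threshold gave 0.0297 for hepatocyte secreted proteins, 0.0140 for hepatic transcription factors, 0.0941 for lymphoid and 0.808, turned, for megakaryocyte genes. CpG-matched lists lowered the lists below background from 12 to 6: coagulation and complement 0.795, mature hepatocyte metabolism 0.469, macrophage 0.504, granulocyte 0.164, lymphoid 0.432, and epidermis, lung, pancreas and gut 0.164. By construction, the background there is genes of the same CpG class. Over all settings these 6 ranged up to those values from 0.00128, 6.86e-04, 4.61e-04, 5.76e-04, 0.00514 and 5.03e-04. There, secreted proteins (0.504) and megakaryocyte genes (0.270) turned, as did secreted proteins in the pooled list (0.743). For megakaryocyte genes with peaks in both lists (1) the corrected odds ratio changed sign, but the share stayed below other genes (33.3% against 34.2%). Leaving out 1 replicate gave 0.00128 to 0.0649 for coagulation and complement, 0.705 to 0.851 for secreted proteins and 0.682 to 1 for megakaryocyte genes.

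For distal lists, heme synthesis passed with the pooled list (0.0182), 20000 bp (0.00672), no matching (0.0298) and either replicate left out (0.00288 to 0.0490). With neighbours counted once (added) heme synthesis gave 0.0374, but that setting left its 12 genes and mean of 4.50 unchanged. The move from 0.0528 came with a new draw of random lists. It therefore shows no effect of neighbours, and the main call depends on the draw. Stem and progenitor genes passed with the pooled list (0.0352) and 100000 bp (0.00960), and ranged from 0.0160 to 0.106 with a replicate left out. Over all settings heme synthesis ranged up to 0.442 and stem and progenitor genes up to 0.371. Lists above matched lists then numbered 4 in the pooled list and 3 to 4 with a replicate left out. Directions turned, none passing, with the strict threshold for secreted proteins (0.858), cholesterol synthesis (1), endothelial (0.847) and epidermis, lung, pancreas and gut (0.847). They turned with peaks in both lists for secreted proteins, cholesterol synthesis and endothelial genes (0.983 each), and in the pooled list for cholesterol synthesis (0.957). At 100000 bp they turned for secreted proteins (0.862), hepatic transcription factors (0.891), macrophage (0.720) and muscle (0.368), and at 20000 bp for cholesterol synthesis (0.976), granulocyte (1) and epidermis, lung, pancreas and gut (0.976). Without matching they turned for secreted proteins (0.951), endothelial (1) and biliary genes (0.951). With a replicate left out, secreted proteins ranged from 0.914 to 0.964, endothelial from 0.896 to 0.914 and biliary from 0.882 to 0.964.

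For motifs within 100 bp of the summit, GATA (0.887), NF-E2 (0.150) and FOXA (0.0656) lost their call, HNF4 (0.0241) and, lower in peaks, CTCF (0.0197) gained one, and KLF (0.0197, lower in peaks), CEBP (0.0578), MEF2 (0.523) and REST (0.909) turned. Those were the highest values of GATA, NF-E2 and FOXA, which ranged from 6.55e-86, 2.28e-37 and 2.95e-08. Flanks 2000 bp from peak edges gave ETS 0.0257 and HNF4 0.0130, with CTCF and MEF2 turned (0.929 each). ETS also passed in the pooled list (0.00365) and ranged from 4.61e-05 to 0.0871 with a replicate left out. CTCF turned at the strict threshold (0.909) and ranged from 0.419 to 0.822, MEF2 turned there (0.750) and with peaks in both lists (0.958) and ranged from 0.866 to 0.888. At 20000 bp the lineage comparison turned for GATA-E-box and HNF4 (1 each). For MEF2 and REST (1 each) the corrected odds ratio changed sign, but both shares stayed higher near erythroid genes. Of 680 values for named genes, 638 kept their promoter status. Depth, which is unknown, limits the calling of weak peaks, so an unmarked promoter is a promoter without a called peak. No paired analysis was possible because there was 1 group.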

Other observations

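The tests of peak width, of gene families, of signal at hepatic promoters, of CpG class, of the strongest decile and of GATA sites beside summits were chosen only after the results they bear on were seen. For the 3 patterns weighed last, no biological difference between groups was tested, since the design has 1 group. Peaks of at least 4000 bp set heme synthesis apart further. There were 671 such peaks in the replicated list, and they lay at the promoters of 429 of 21938 genes (1.96%). Of the 21938 genes, only 8284 had any promoter peak, so part of each contrast with other genes repeats the promoter marking. Wide peaks at promoters were not counted in each replicate's list. Heme synthesis had them at 11 of 12 genes (Fisher's exact test, adjusted p = 3.99e-17), with Urod, which was chosen after its values were seen, as the exception. Erythroid genes had them at 9 of 23 (adjusted exact p = 1.97e-09), among them the transcription factor genes Gata1, Klf1, Gfi1b and Nfe2 and the anion exchanger gene Slc4a1. Stem and progenitor genes had them at 3 of 20, Tal1, Lmo2 and Lyl1 (adjusted exact p = 0.0397). Globins did not pass, with 1 of 10, Hba-a2 (adjusted exact p = 0.844). The 4 hepatic lists, ribosomal proteins, proteasome and cell cycle had 0 (adjusted exact p = 1 each), which at 1.96% of all genes shows no depletion.

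Gene families taken from symbols gave further contrasts against CpG-matched random lists. Histone genes were marked at 61 of 67 promoters (91.0%, against 64.6% of matched genes), mitochondrial ribosomal proteins at 66 of 78 (84.6% against 53.7%) and respiratory complex I at 38 of 46 (82.6% against 55.3%), with permutation test adjusted p = 4.50e-04, 4.50e-04 and 6.00e-04. Zinc finger genes named Zfp were marked at 190 of 394 (48.2% against 41.6%, adjusted permutation p = 0.00746). Keratins were marked at 1 of 53, vomeronasal receptors at 1 of 331, beta defensins at 0 of 42 and clustered protocadherins at 0 of 57 (adjusted permutation p = 6.00e-04, 4.50e-04, 0.00922 and 4.50e-04). Solute carriers did not pass (128 of 371, adjusted permutation p = 0.0644). Families whose genes lie in clusters were counted gene by gene, which these p-values do not allow for. On chromosome X, 198 of 948 promoters were marked (20.9% against 30.2% of CpG-matched genes, permutation test, p = 2e-04, the smallest the random lists can give). Matching covered CpG class alone. The number of X copies in pools of mixed sex, mappability and the kinds of genes on X were not accounted for. The lower share of called peaks therefore does not show lower acetylation.

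The replicated list held regions that were not in both replicate lists. Of its 26594 peaks, 19583 overlapped a peak of both lists by at least 1 bp, 4721 of replicate 1 alone, 1167 of replicate 2 alone and 1123 of neither. Their median signals were 5.32, 3.27, 3.28 and 3.01. No pooled peak that overlapped both replicate lists by 50% of either peak was missing from the replicated list (0 of 19467).

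Replicate 1 peaks missing from replicate 2 are a pattern with 3 candidate explanations that were weighed with values, and a further one that could not be. Different shares of erythroid and hepatic cells in the pools could change recovery by lineage. Recovery was 61.6% for 430 peaks near erythroid or globin genes and 53.1% for 177 peaks near hepatic genes. At equal signal decile the difference was 1.73 percentage points (95% bootstrap interval -4.44 to 8.30), within the 10 points set as the bound. That bound was not derived from a known change in cell shares, and neighbouring peaks were resampled as independent. A shift in cell shares therefore stays open. GC content of missing distal peaks was -0.33 percentage points from that of found ones at equal signal (interval -0.52 to -0.14), under the bound of 1. Weaker enrichment or lower depth in replicate 2 stays open: 100% of the strongest decile were found, but recovery was already 96% in decile 8, so this value cannot decide. The additional input file behind the replicate 1 list stays open too, as it differs between the replicates in the same way.

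Low marking of hepatic promoters beside erythroid ones is the second pattern. CpG class alone would leave both groups level once matched, but erythroid, globin and heme genes (44 of 45 marked, 27.6% in matched lists) exceeded the 4 hepatic lists (15 of 83, 18.1%, against 21.3% in matched lists) by 73.5 percentage points after matching. Whether CpG class accounts for the level of the hepatic lists themselves stays open: the pooled test did not pass (permutation test, p = 0.506), but secreted proteins lay above matched lists (30.0% against 21.4%) and mature hepatocyte metabolism below (8.33% against 16.7%). Acetylation in few of the cells may weaken hepatic promoter signal: the 15 marked hepatic genes had a median of 3.47, below the 4.22 to 9.68 that held 95% of matched lists of marked genes. The cell makeup of the pools was not measured here, so a low level of acetylation in most hepatic cells stays open, and the hypothesis rests on these same data.

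Loss of the GATA excess within 100 bp of summits is the third pattern. At 100 to 250 bp from the summit, distal peaks held 0.342 GATA sites per kb against 0.132 in flanks, while within 100 bp they held 0.145 against 0.144, a difference in excess of 0.21 per kb (interval 0.183 to 0.236). That difference follows from the pattern itself, so it does not test whether sites lie beside summits, which stays open. The reversed motif showed the same direction at 0.051 per kb (interval 0.0302 to 0.0719), so base composition around summits may account for part of the difference.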
